A study of Homo sapiens with 5 samples.

How the data were processed

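RNA from cultured primary epidermal keratinocytes was sequenced in 5 libraries: proliferating cells, cells differentiated in 1.8 mM calcium, and calcium-treated cells with siRNA against IRX2, IRX4 or IRX5. Per the labels, siRNAs were used as pools at 30 nM, calcium was added 12 hours after transfection, RNA was collected at 72 hours with an integrity number above 8, and single-end reads came from an Illumina HiSeq; both a SMARTER and a TruSeq kit are named. The labels give no siRNA for the differentiated control. The 72 hours apply to the calcium-treated libraries, and no collection time is recorded here for the proliferating library. IRX3 knockdown, which the protocol also names, was not analysed here.

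The deposited values are FPKM, computed by the authors from read counts per gene. Per the submitters' processing notes, reads were aligned to hg38 with Bowtie2 and DESeq2 was used, without versions; the read counter, the annotation and the strand setting are not stated in the sources used here. The deposited table held 25242 entries: 5 summary lines of the read counter and 25237 genes, of which 5707 were 0 in all libraries. Per library, in the order proliferating, control, siIRX2, siIRX4 and siIRX5, the summary lines put 6.73, 7.37, 7.11, 8.01 and 8.21% of reads outside any gene, 1.98, 1.82, 1.98, 1.82 and 1.93% in overlapping genes and 5.52, 5.68, 5.94, 5.81 and 6.22% at several places. Sample columns left unused: 0.

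Whole read counts were recovered from the FPKM values, since each gene's values across libraries are whole multiples of a common unit once the library totals are known; every value above 0 lay within 1.4e-09 of a whole read. The totals used by the authors were 30592707, 29634652, 27351020, 27515737 and 27566310 reads in the same order, with 17473, 17547, 17604, 17606 and 17514 genes detected. Genes with a length over 1 base held all but 1.66 to 1.92% of these totals, and with the others the sum exceeded the total (30896794 reads in the proliferating library), for a reason not given in the sources used here. Counts are the smallest whole numbers that give a gene's values, so true counts can be a multiple. Plain ratios of reads do not depend on this, and their intervals are then wider than needed. Minimums in reads, and log2 ratios by reads with a pseudocount of 1 read, can depend on it. The lengths behind the FPKM values were within 10% of the GENCODE 29 gene span for 63.7% of 16894 genes, so most FPKM values are per base of the genomic span, introns included; they are not comparable between genes, and a minimum in FPKM leaves out long genes. For 2055 genes the length was 1 base, and these were left out wherever FPKM was used. Symbols changed to dates by a spreadsheet (27 with reads) identify no gene and were not named.

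The comparison of calcium differentiation set the control against the proliferating library, and each knockdown was set against the control; the 3 knockdowns were also compared with each other. These choices, the 31 gene lists and the alternatives were fixed before the data were examined. With 1 library per group no test, standard error or p-value was computed. Genes with at least 1 FPKM in 1 or more libraries (6940) were counted as apart at a 2-fold difference of FPKM plus a pseudocount of 1. Ratios of reads per 1000000 (RPM) are given with exact conditional binomial 95% intervals, which cover counting error and no biological or preparation differences. For a gene with 171 reads in the control and 33 in a knockdown, such as IRX5, this interval ran from 0.138 to 0.303. A list's median was placed among 10000 random lists of the same size drawn from 20 bins of expression, and a list stood apart below percentile 1 or above percentile 99; percentiles describe these libraries and not a population. The lists cover epidermal layers, lipid barrier and transcription factors, cell cycle, DNA repair and p53, signalling, stress, metabolism, inflammation, ribosomal proteins and histones, and markers of fibroblasts, melanocytes, endothelium and immune cells. No list of mitochondrial genes was tested, since the table held 0 of them.

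Named genes were, in each comparison, the 8 with the largest positive and the 8 with the largest negative difference among genes with at least 5 FPKM in 1 of both libraries, all IRX genes, BRCA1 and FGF18, the 3 members with the largest difference in each list that stood apart, and a fixed set of keratinocyte genes for differentiation. Small RNA genes with few reads took many of these places and are given as counts, and some other genes that meet the rule are not named. Other members of the fixed lists, and a ranking of protein-coding genes by the nearer bound of the read ratio (12 in each direction, at least 200 reads in 1 of both libraries), were chosen after their values were seen.

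The alternatives were a pseudocount of 0.1, no minimum, a minimum of 5 FPKM, libraries rescaled to a sum of 1000000 (which multiplies all values by 9.25 to 9.77 against a fixed pseudocount and minimum), a median log2 ratio of 0, quantile normalization, a threshold of 1.5-fold and the mean of the other calcium-treated libraries as comparator. After seeing the data, recovered RPM (a pseudocount of 1 read, genes with a mean of at least 10 reads, 14291 genes, those with a length of 1 base included) and a comparator without siIRX2 were added, as was the other comparator by reads. The chance similarity of knockdowns that share a control was simulated 100 times with independent noise at the spread of the 4 calcium-treated libraries. Words of 7 bases in annotated 3' untranslated regions were scanned in each calcium-treated library against the mean of the other calcium-treated libraries. The log2 ratios of reads were limited to 2 in size and adjusted for the length and GC content of the 3' untranslated region and for expression. Genes with and without each word were then compared (15667 words in at least 100 of 10941 genes with a mean of at least 50 reads).

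The rules were tested on simulated data. The simulated reads held counting error alone, without culture or preparation differences, so calls of unchanged genes are not error rates between single cultures. Of genes made 3-fold apart, the FPKM rule found 67.2, 76.1, 77.6 and 79.1% in the 4 comparisons (differentiation, siIRX2, siIRX4, siIRX5) and the read rule 98.5, 97.0, 98.5 and 98.5%; both found 100% at 6-fold. Of unchanged genes, 15, 15, 11 and 17 were called by FPKM (0.246, 0.246, 0.181 and 0.279%). By reads 57, 58, 64 and 77 were called (0.405, 0.412, 0.455 and 0.547%). The simulations held 6288 genes for FPKM and 14278 for reads, the changed genes included. Random lists stood apart in 0, 0, 1 and 0 of 100 draws, and a list lowered by 0.3 lay at percentile 0 in each comparison. Intervals covered the true ratio in 96.8% of 2000 draws, and a lowered word ranked at the top in 10 of 10 scans. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and biopython 1.88 were used.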

Results

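Cultured primary human epidermal keratinocytes were sequenced as 5 libraries, 1 per group: proliferating cells, cells differentiated in 1.8 mM calcium without a stated siRNA, and calcium-treated cells in which the Iroquois homeobox gene IRX2, IRX4 or IRX5 was targeted with 30 nM of pooled siRNA. No group had a replicate, so every difference below is a difference between libraries and carries no test of the condition. Ratios are of recovered reads per 1000000 of the library total (RPM), with the 95% interval of counting error alone in parentheses; no molecular identifiers are named for the reads. The labels give no transfection for the differentiated control, so a difference between a knockdown library and this control can include the transfection itself. No collection time is recorded here for the proliferating library, so its comparison with the control was not known to be matched in time.

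The targeted genes were compared ahead of all others. IRX2 (chromosome 5, 2745845 to 2751662), IRX4 (chromosome 5, 1877413 to 1887236) and IRX5 (chromosome 16, 54930862 to 54934485; GRCh38, GENCODE 29) each had their lowest value among the 5 libraries in the library named for them. IRX2 was at 2.30 FPKM in the siIRX2 library and 3.72 in the control, a ratio of 0.618 (0.540 to 0.706). IRX4 was at 0.458 FPKM in the siIRX4 library and 2.02 in the control, a ratio of 0.226 (0.185 to 0.275), and IRX5 at 0.364 in the siIRX5 library and 1.76 in the control, a ratio of 0.207 (0.138 to 0.303). IRX4 and IRX5 mRNA were thus 77.4% and 79.3% lower than in the control, and IRX2 mRNA 38.2% lower (29.4% to 46.0%), short of the 70% that the protocol set when single siRNAs were chosen for pooling. IRX4 was higher in the siIRX2 library, at 1.57 (1.41 to 1.74) times the control. The other cross-comparisons of the 3 targets, from IRX5 in the siIRX4 library at 0.913 (0.727 to 1.15) to IRX5 in the siIRX2 library at 1.20 (0.974 to 1.49), had intervals that included 1. Of the family members that were not targeted, IRX3 (chromosome 16, 54283304 to 54286763) was at 0.781 (0.605 to 1.01) in the siIRX5 library and IRX1 (chromosome 5, 3596054 to 3601403) at 0.818 (0.563 to 1.18), while IRX6 (chromosome 16, 55323760 to 55330760) had 0 reads in all 5 libraries.

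**Figure D1:**
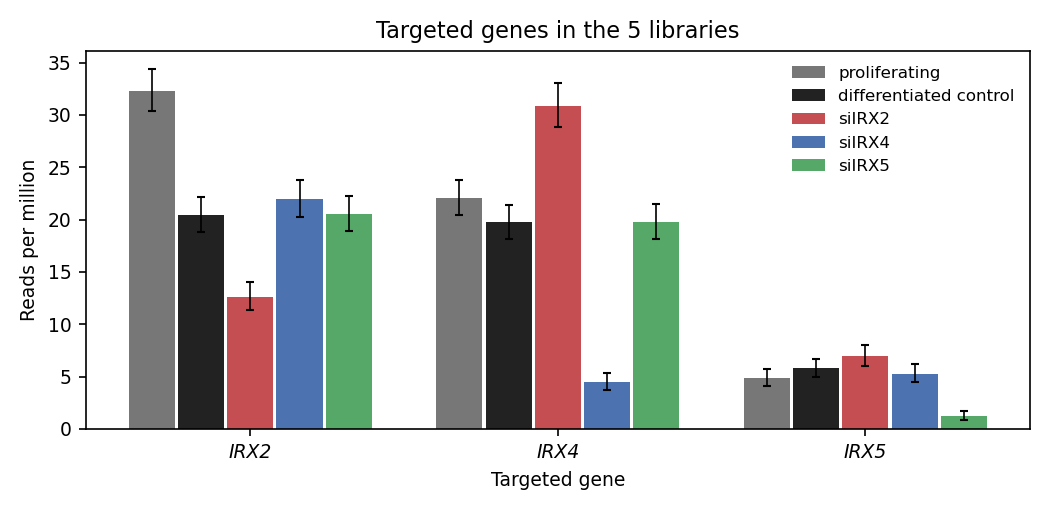
IRX2, IRX4 and IRX5 in each of the 5 libraries, in recovered RPM of the authors' read totals. Bars give the single library of each group and whiskers the exact Poisson 95% interval of its read count. Each gene was lowest in the library in which it was targeted.

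Calcium differentiation was marked by genes of the outer epidermis. SPRR2F, a cornified envelope precursor, was 52.3 (38.0 to 74.2) times higher in the differentiated than in the proliferating library, and S100A7, an antimicrobial protein of the upper epidermis, 31.5 (25.9 to 38.6) times. The same held for WFDC12 38.8 (29 to 53), CST6 25.2 (20.1 to 31.9) and SPRR2G 23.4 (18.2 to 30.5), where CST6 is a protease inhibitor of the stratum corneum, and for C6orf15 19.7 (17.0 to 22.8), KLK7 17.6 (17.0 to 18.2) and PI3 15.6 (14.6 to 16.6), where KLK7 is a protease of corneocyte shedding and PI3 (elafin) an elastase inhibitor. TGFBI, an extracellular matrix protein, was lower in the differentiated library at 0.0924 (0.0875 to 0.0975), as were KCNMA1 0.111 (0.0819 to 0.147), SLAMF9 0.180 (0.144 to 0.222) and NDRG1 0.269 (0.264 to 0.274). In total 374 of 6940 genes were at least 2-fold apart, 284 higher and 90 lower in the differentiated library, and for 329 of them the interval of the read ratio excluded 1. By reads, where 14291 genes were measured, 1782 were. Small RNA genes made up 69 of the 374, with a median of 7 reads in the larger library. Among the other genes 256 were higher and 49 lower.

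Of the cornified envelope list, 39 genes were measured by FPKM, and 31 of them were at least 2-fold higher (median log2 ratio 2.07, percentile 100 of lists matched on expression). The spinous layer list was higher as well (median log2 ratio 1.10, percentile 100; median log2 ratio 1.99 by reads, percentile 100), with SBSN 9.12, CALML5 6.98 and KRTDAP 6.07. Involucrin (IVL) was at 6.16 (5.98 to 6.35), transglutaminase 1 (TGM1) at 6.14 (5.67 to 6.66) and filaggrin (FLG) at 3.31 (2.95 to 3.73). Keratin 1 had 92 reads against 1, a ratio of 95.0 with an interval from 16.6 to 3792. KRT10 was at 1.29 (1.09 to 1.53), and loricrin had 3 reads in the differentiated and 0 in the proliferating library. Basal keratinocyte genes were lower (median log2 ratio -0.46, percentile 0), among them COL7A1 at 0.402 and DST at 0.424, which anchor basal cells to the basement membrane. The basal keratins KRT5 and KRT14 were at 0.788 (0.785 to 0.792) and 0.919 (0.914 to 0.923), and KRT15 was higher at 2.05 (2.02 to 2.08). Differentiation transcription factors (median log2 ratio 0.46, percentile 99.99) included HOPX 5.78 and ELF3 4.83 above and MAF at 0.408 below the proliferating library. Epidermal lipid barrier genes stood at percentile 95 by FPKM, with 9 measured, and apart by reads, with 23 measured (median log2 ratio 0.96 by reads, percentile 100).

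Proliferation genes were lower in the differentiated than in the proliferating library. The mitosis list had 19 genes measured by FPKM (median log2 ratio -0.57, percentile 0) and the DNA replication list 17 (median log2 ratio -0.41, percentile 0), with MKI67 0.457 (0.433 to 0.483), CCNA2 0.483 (0.436 to 0.536) and CDC20 0.5 (0.460 to 0.543) for mitosis and TK1 0.460 (0.410 to 0.514), RRM2 0.523 (0.486 to 0.562) and MCM7 0.600 (0.566 to 0.636) for replication. Lower lists also included hypoxia and glycolysis (median log2 ratio -0.57, percentile 0; CA9 0.228 and VEGFA 0.484), unfolded protein and amino acid stress (median log2 ratio -0.42, percentile 0; ASNS 0.428, PHGDH 0.415 and HSPA5 0.549) and ribosomal proteins (median log2 ratio -0.42, percentile 0; 73 of 74 lower, RPSA 0.606, RPL10 0.633 and RPS18 0.643). Higher lists included wound keratins and alarmins (median log2 ratio 0.66, percentile 99.99; S100A9 10.6), cholesterol synthesis (median log2 ratio 0.38, percentile 99.91; MVD 2.42, FDPS 2.11 and MSMO1 1.76) and replication-dependent histones (median log2 ratio 0.30, percentile 99.98; not apart by reads, percentile 98.3). The last of these were led by HIST2H2BE at 3.28 (3.02 to 3.57) and HIST1H2AC at 1.93 (1.71 to 2.18), and HIST3H2BB had 17 reads against 1. The lists of SPRR and LCE genes, histones and small RNAs hold close copies or overlapping genes, so the counts of single members are uncertain. In all, 12 of 27 lists stood apart, where 0.54 would if the lists were genes drawn at random. Genes of a list can shift together, so the number expected between single cultures without an effect is not known. BRCA1 (chromosome 17, 43044295 to 43170245), a gene of homologous recombination, was at 0.515 (0.461 to 0.575), and FGF18 (chromosome 5, 171419656 to 171457623) had 9 reads against 23. By reads, the lists of homologous recombination (21 genes, median log2 ratio -0.49 by reads, percentile 0.07), Fanconi anaemia (15 genes, median log2 ratio -0.56 by reads, percentile 0.05), DNA damage checkpoint (18 genes, median log2 ratio -0.38 by reads, percentile 0.19) and p53 targets (21 genes, median log2 ratio -0.26 by reads, percentile 0.785) were lower in the differentiated library too; by FPKM, with 3, 5, 9 and 18 genes measured, these lists did not stand apart (percentiles 9.7, 4.53, 13.6 and 1.91).

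Keratinocytes targeted for IRX2 had the chemokines CXCL3 and CXCL5 above the control, at 5.82 (4.85 to 7.01) and 3.78 (3.27 to 4.38) times. Below the control stood the growth factor-like IGFL1 at 0.167 (0.137 to 0.203), the choline transporter SLC44A2 at 0.217 (0.212 to 0.222), the cytokine CSF2 at 0.199 (0.167 to 0.237) and PHLDA1 at 0.284 (0.273 to 0.294). Mitosis genes were the lowest list (median log2 ratio -0.65, percentile 0; median log2 ratio -1.56 by reads, percentile 0). UBE2C was at 0.264 (0.211 to 0.329), CCNA2 at 0.269 (0.221 to 0.326) and CDC20 at 0.365 (0.318 to 0.417), and by reads all 30 members were lower, 26 of them at least 2-fold. DNA replication genes were lower too (median log2 ratio -0.40, percentile 0), with RRM2 0.262 (0.229 to 0.3), CDT1 0.321 (0.243 to 0.419) and MCM7 0.609 (0.563 to 0.658). In total 121 genes were at least 2-fold apart, 50 higher and 71 lower, and 78 had a read ratio whose interval excluded 1; by reads the number was 1072. Small RNA genes (SNORD and MIR) made up 59 of the 121, with a median of 6 reads in the larger library, and among the other genes 16 were higher and 46 lower.

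Cornified envelope genes were lower than in the control (median log2 ratio -0.50, percentile 0), with SPRR2G 0.345 (0.310 to 0.383), CDSN 0.379 (0.341 to 0.421) and LCE3E 0.410 (0.347 to 0.483), as were differentiation transcription factors (median log2 ratio -0.21, percentile 0.07), with ELF3 0.508, OVOL1 0.630 and PRDM1 0.668. Genes of the unfolded protein and amino acid stress response were lower (median log2 ratio -0.26, percentile 0.02; CHAC1 0.434, XBP1 0.536 and HSPA5 0.710). Hypoxia and glycolysis genes were higher (median log2 ratio 0.25, percentile 99.91), with the carbonic anhydrase CA9 at 3.76 (3.01 to 4.73), and so were 69 of 74 ribosomal protein genes (median log2 ratio 0.30, percentile 100; RPL11 1.54), although RPL15 and RPS27A were at 0.475 (0.465 to 0.486) and 0.656 (0.637 to 0.675). Inflammatory cytokines stood inside the range of random lists by FPKM (percentile 93.6) and above it by reads (median log2 ratio 0.53 by reads, percentile 100), with IL33 3.96, CXCL1 1.90 and PTGS2 2.27 among 13 of 19 higher genes. BRCA1 was at 0.505 (0.429 to 0.592). The homologous recombination list was lower by reads (median log2 ratio -0.41 by reads, percentile 0.16), with BRCA2 at 0.317, and so were Fanconi anaemia (median log2 ratio -0.51 by reads, percentile 0.04) and checkpoint genes (median log2 ratio -0.35 by reads, percentile 0.07), while p53 targets were higher (median log2 ratio 0.19 by reads, percentile 99.72; 17 of 21 higher). By FPKM none of these 4 lists stood apart (percentiles 83, 2.38, 4.46 and 85.6), and the 3 homologous recombination genes measured had a median of 0.10. FGF18 had 0 reads in this library and 9 in the control. By FPKM 7 of 27 lists stood apart.

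Late cornified envelope (LCE) genes were higher in cells targeted for IRX4, with 13 of 14 above the control and a median ratio of 1.97. LCE1A was at 2.72 (2.43 to 3.05) times the control, SPRR4 at 2.56 (2.27 to 2.90) and LCE2B at 2.55 (1.91 to 3.44). LCE6A, which is not among these 14, was at 3.65 (2.83 to 4.74). It was higher in the siIRX2 library as well, at 2.70 RPM in the control, 8.92 in siIRX2 and 9.85 in siIRX4. The mucosal keratin KRT13 was lower at 0.473 (0.461 to 0.485). The cornified envelope list was higher (median log2 ratio 0.29, percentile 100), and by reads 29 of its 44 measured genes were higher, 10 of them at least 2-fold; its SPRR genes split 5 to 5. The spinous layer list was also higher (median log2 ratio 0.25, percentile 99.99), with KRTDAP 1.59 (1.49 to 1.70) and SBSN 1.41 (1.38 to 1.44), but CALML5 at 0.671 (0.619 to 0.727). In total 67 genes were at least 2-fold apart, 41 higher and 26 lower, and 61 of these were small RNA genes with a median of 5 reads, which left 6 others, 4 higher and 2 lower. For 23 of the 67 the interval excluded 1, and by reads 328 genes were at least 2-fold apart.

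Wound keratins and alarmins were higher in this library (median log2 ratio 0.092, percentile 99.66), with PI3 at 2.12 (2.08 to 2.16) and KRT6C at 1.93 (1.73 to 2.16), while S100A9 was at 0.652 (0.643 to 0.661). Basal keratinocyte genes were slightly higher as a list (median log2 ratio 0.089, percentile 99.52), with ITGA6 at 1.26, KRT15 at 0.855 and ITGA2 at 0.814. Stress response genes were higher too (median log2 ratio 0.10, percentile 99.68; DDIT3 1.35, ASNS 1.34 and SESN2 1.32). Mitosis (median log2 ratio -0.15, percentile 0) and DNA replication (median log2 ratio -0.16, percentile 0) were lower than in the control, with KIF20A 0.731 (0.633 to 0.844), CDK1 0.739 (0.649 to 0.842) and PLK1 0.759 (0.664 to 0.867) for mitosis and RRM2 0.675 (0.613 to 0.742), CDT1 0.700 (0.569 to 0.859) and FEN1 0.805 (0.720 to 0.898) for replication. These differences were smaller than those of the siIRX2 library, and both medians turned positive against the mean of the other calcium-treated libraries. With siIRX2 left out of that mean, mitosis no longer stood apart (-0.038, percentile 29.1) and DNA replication did (-0.10, percentile 0.77). BRCA1 was at 0.874 (0.763 to 1.001) and FGF18 had 5 reads against 9. By reads the homologous recombination (median log2 ratio -0.20 by reads, percentile 0.1; 14 of 21 lower, 4 intervals below and 2 above 1) and Fanconi anaemia (median log2 ratio -0.21 by reads, percentile 0.18; 13 of 15 lower) lists were lower, and by FPKM neither stood apart (percentiles 57.8 and 3.35). By FPKM 7 of 27 lists stood apart.

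Cells targeted for IRX5 had far fewer reads of late cornified envelope genes than the control. LCE3E was at 0.136 (0.104 to 0.175), LCE3D at 0.279 (0.247 to 0.315) and SPRR3 at 0.286 (0.274 to 0.299), and 31 of the 39 cornified envelope genes measured were lower (median log2 ratio -0.50, percentile 0). Others among the 8 lowest genes were the matrix metalloproteinases MMP9 at 0.236 (0.221 to 0.251) and MMP10 at 0.403 (0.389 to 0.417), CSF2 at 0.227 (0.192 to 0.267), PRR9 at 0.281 (0.250 to 0.316) and the decoy receptor IL1R2 at 0.284 (0.266 to 0.302). ID3, an inhibitor of basic helix-loop-helix factors, was higher at 2.81 (2.5 to 3.17). In total 111 genes were at least 2-fold apart, 62 higher and 49 lower, and the interval excluded 1 for 59; by reads the number was 635. Small RNA genes were 73 of the 111, including 7 of the 8 highest, with a median of 6 reads, and among the other 38 genes 13 were higher and 25 lower. The balance of higher and lower genes among the 111 depended on the scaling, with 52 higher and 54 lower when the median log2 ratio was set to 0.

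Several groups of epidermal genes stood below the control in the siIRX5 library. Basal keratinocyte genes (median log2 ratio -0.14, percentile 0.09) included the laminin chain LAMA3 at 0.535 (0.531 to 0.539) and the collagen receptor subunit ITGA2 at 0.528 (0.517 to 0.539). Interferon response genes (median log2 ratio -0.18, percentile 0) included IFIT3 0.421 (0.396 to 0.447), CXCL11 0.369 (0.242 to 0.550) and CXCL10 0.465 (0.328 to 0.651). Inflammatory cytokines (median log2 ratio -0.27, percentile 0) included TNF at 0.562 (0.464 to 0.680), but IL33 at 3.17 (2.53 to 4.01). The WNT signalling list was lower by FPKM (median log2 ratio -0.16, percentile 0.19), with DKK1 0.556, FZD10 0.393 and WNT7B 0.652, and not apart by reads (median log2 ratio -0.15 by reads, percentile 2.92). Mitosis (median log2 ratio -0.19, percentile 0.01) and DNA replication (median log2 ratio -0.17, percentile 0) were lower, with FOXM1 0.565 (0.490 to 0.651), UBE2C 0.651 (0.554 to 0.762) and KIF20A 0.723 (0.625 to 0.834) and GINS2 0.577 (0.453 to 0.731), CDT1 0.624 (0.503 to 0.771) and RRM2 0.752 (0.686 to 0.825), and as in siIRX4 both medians turned positive against the mean of the other calcium-treated libraries. With siIRX2 left out of that mean, mitosis stood apart (-0.11, percentile 0.19) and DNA replication did not (-0.07, percentile 1.9). All 74 ribosomal protein genes measured were higher (median log2 ratio 0.34, percentile 100; RPSA 1.53, RPS3 1.47 and RPS2 1.40). By FPKM 8 of 27 lists stood apart.

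The series title relates IRX5 to DNA damage repair and hair follicle stem cells, and both were compared in the siIRX5 library. BRCA1 was at 0.859 (0.750 to 0.984) and FGF18 had 5 reads against 9, a ratio of 0.597 (0.157 to 1.98). Homologous recombination genes (median log2 ratio -0.16 by reads, percentile 1.24) did not stand apart; 7 of 21 had an interval below 1, such as RAD51AP1 0.563, BARD1 0.690 and BRCA2 0.703, and 2 an interval above 1, RAD51B at 1.40 and RBBP8 at 1.13. Neither did the other repair lists: Fanconi anaemia (median log2 ratio -0.068 by reads, percentile 13.3), nucleotide excision repair (median log2 ratio 0.031 by reads, percentile 39.2), base excision and mismatch repair (median log2 ratio 0.0069 by reads, percentile 30.2), non-homologous end joining (median log2 ratio 0.045 by reads, percentile 48.4), and DNA damage checkpoint (median log2 ratio -0.037 by reads, percentile 13.9). The p53 targets lay just inside the bound of percentile 99 (median log2 ratio 0.18 by reads, percentile 98.7), with 16 of 21 higher and 15 intervals above 1. Hair follicle stem cell genes were at percentile 1.07 by FPKM, with 5 measured, and lower by reads, with 11 measured (median log2 ratio -0.31 by reads, percentile 0.19); 8 of the 11 were lower, among them NFATC1 at 0.637 (0.498 to 0.811), RUNX1 at 0.745 (0.704 to 0.788) and SOX9 at 0.817 (0.788 to 0.846), factors of hair follicle stem cells. The FGF signalling list had no common direction: by FPKM its 8 measured genes did not stand apart (median log2 ratio 0.18, percentile 92.5), and by reads its median was lower (median log2 ratio -0.22 by reads, percentile 0.15) with 8 genes higher and 9 lower, 7 intervals above and 7 below 1. Among these FGFR3 was at 2.97 (2.72 to 3.25) and FGFBP1 at 1.98 (1.93 to 2.02). The BMP and TGF-beta list was lower by reads (median log2 ratio -0.18 by reads, percentile 0.54; INHBA 0.470) and not apart by FPKM (median log2 ratio -0.096, percentile 1.25).

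**Figure D2:**
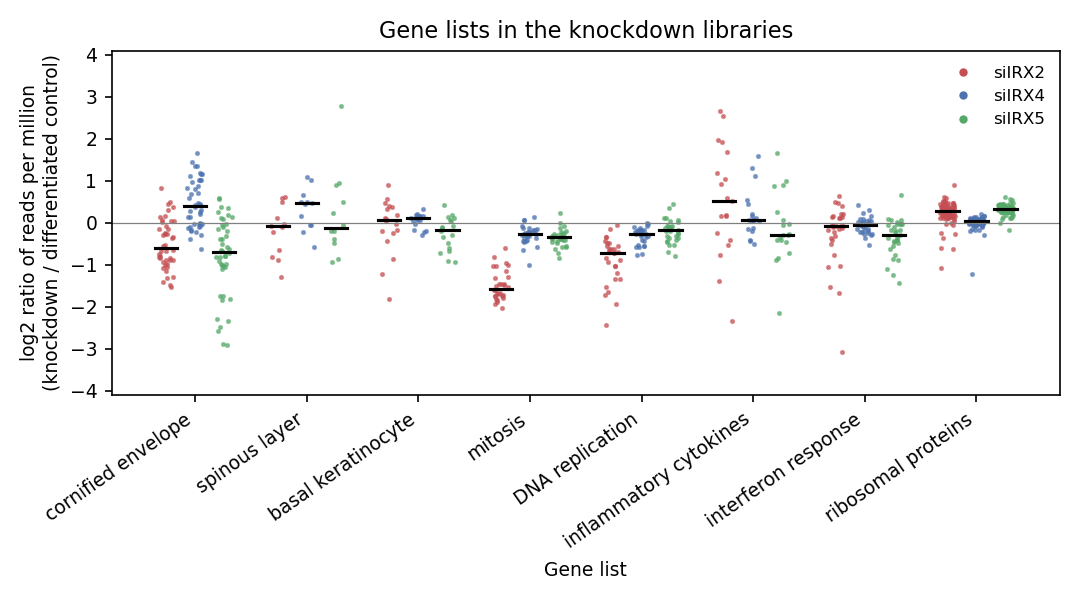
Log2 ratios of recovered RPM for single genes of selected lists, siIRX2 (red), siIRX4 (blue) and siIRX5 (green) against the differentiated control. Dots are genes with a mean of at least 10 reads per library, black bars are the medians of the plotted genes, and the grey line marks equal levels. Each library is a single sample. The cornified envelope list was lower in siIRX2 and siIRX5 and higher in siIRX4.

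The knockdown libraries were also compared directly, which leaves out the control, whose transfection is not given, but still compares libraries, not conditions. Cornified envelope genes were lower in siIRX2 than in siIRX4 (median log2 ratio by reads -0.80) and higher in siIRX4 than in siIRX5 (1.21, 36 of 44 genes higher). Between siIRX2 and siIRX5 their median was 0.39, but members went both ways, 26 higher and 18 lower in siIRX2, with 18 intervals above and 16 below 1. Mitosis genes were lower in siIRX2 than in siIRX4 (-1.25) and siIRX5 (-1.19). Inflammatory cytokine genes were lower in siIRX5 than in the other knockdowns (0.44 for siIRX2 and 0.42 for siIRX4 over siIRX5). Between siIRX2 and siIRX4 these cytokine genes did not stand apart (0.12, percentile 92.3), with 11 higher and 8 lower in siIRX2. Ribosomal protein genes were lower in siIRX4 than in siIRX5 (-0.32). Hair follicle stem cell genes, lower by reads in siIRX5 than in the control, did not stand apart here. Their medians were 0.16 for siIRX2 over siIRX5 (percentile 94.8) and 0.11 for siIRX4 over siIRX5 (percentile 93.1). In each comparison 6 of these genes were lower in siIRX5 and 5 higher. By FPKM 109 genes were at least 2-fold apart between siIRX2 and siIRX4, 170 between siIRX2 and siIRX5 and 126 between siIRX4 and siIRX5.

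Sharing a control makes knockdown differences alike without any effect. Across 6940 genes, which are not independent replicates, the differences correlated at r = 0.392 for siIRX2 and siIRX4, 0.337 for siIRX2 and siIRX5 and 0.307 for siIRX4 and siIRX5, and each r was below the 0.5, 0.501 and 0.5 of simulated unchanged libraries with a common control. The simulated r follows from giving every library equal noise. The spread used also holds the differences between the knockdowns, so neither r nor the covariance shows whether the knockdowns share an effect. The covariances were 0.0274, 0.0316 and 0.0184, against 0.0459, 0.0461 and 0.0460 simulated. Genes at least 2-fold higher in both numbered 17, 13 and 11, against 1.37, 1.38 and 1.36 simulated and 0.295, 0.447 and 0.366 for independent sets. Genes at least 2-fold lower in both numbered 13, 14 and 10, against 1.35, 1.29 and 1.45 simulated and 0.266, 0.501 and 0.184 for independent sets. The simulated noise was normal and set by expression level alone, unlike that of small RNA genes with few reads, so the excess over it cannot be read as a shared effect. By FPKM, 7 genes were at least 2-fold higher and 5 at least 2-fold lower in all 3 knockdowns, and each of the 12 was a small RNA gene with few reads, such as MIR221 and SNORD6.

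Differentiation genes were also chosen without the knockdown or the control under study, from the mean of the other knockdowns against the proliferating library. Of 270 genes higher on differentiation by this rule, 189 were lower in siIRX2 than in the control (median log2 ratio -0.25, percentile 0), and 72 genes lower on differentiation had a median of 0.12 (percentile 99.89). For siIRX4 the medians lay close to 0, at -0.017 for 250 genes higher on differentiation (percentile 0.42) and 0.033 for 91 lower (percentile 99.07). For siIRX5 the 244 genes higher on differentiation had a median of -0.016 and the 84 lower a median of -0.072, both at percentile 0.

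Markers of other skin cell types were low apart from vimentin. The fibroblast marker sum was 1470, 676, 752, 801 and 378 RPM in the proliferating, control, siIRX2, siIRX4 and siIRX5 libraries, nearly all of it vimentin (VIM at 1449, 658, 735, 782 and 364), and without VIM it was 20.4, 17.5, 17.2, 18.4 and 13.9. Melanocyte markers summed to between 6.31 and 13.2 RPM, most of it MITF, and endothelial and immune markers to between 0.588 and 11.8, most of it VWF.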

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

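The tests of members without the 3' untranslated region words and of how many members outside both families were higher in siIRX4 were chosen only after their results were seen.

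Cornified envelope genes stood apart in opposite directions: the median log2 ratio by reads was -0.60 in siIRX2 and 0.40 in siIRX4, a difference of -1.01, and -0.67 in siIRX5, so that siIRX4 exceeded siIRX5 by 1.08. The difference was not tested, since each knockdown had 1 library. Other lists that stood apart in opposite directions were basal keratinocyte genes (0.11 in siIRX4 and -0.16 in siIRX5, difference 0.27), inflammatory cytokines (0.53 in siIRX2 and -0.27 in siIRX5, difference 0.80) and unfolded protein and amino acid stress genes (-0.36 in siIRX2 and 0.15 in siIRX4, difference -0.51); these differences were not tested either. A further signal lay outside the FPKM comparisons: 1128 genes with a length of 1 base had a mean of at least 10 reads, and 109, 57, 20 and 51 of them were at least 2-fold higher and 42, 56, 16 and 25 at least 2-fold lower in the 4 comparisons (differentiation, siIRX2, siIRX4, siIRX5).

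For the cornified envelope, transcript length and GC content was weighed by drawing random lists matched on both and on expression: the list stayed at percentile 0 in siIRX2 and siIRX5 and at 100 in siIRX4, which argues against it. Reads shared between SPRR and LCE copies was weighed on the 20 members outside both families. At percentile 0.01 in siIRX2, with a median of -0.45 and 16 lower and 4 higher, they argue against it there. In siIRX5 their percentile of 0 and median of -0.53, against -0.67 for the whole list, also argue against it. The siIRX5 case is less clear, since 13 of these members were lower and 7 higher. In siIRX4 they were at percentile 99.8, past the bound set in advance, but this does not decide it, since 11 were higher and 9 lower and their median was 0.14 against 0.40 for the whole list, so sharing of reads among copies stays open for siIRX4. Seed matches in the list members themselves was weighed on members without either of the lowest words of the library, with medians of -0.65 in siIRX2 (37 of the 41 members with an annotated 3' untranslated region) and -0.67 in siIRX5 (40 of 41). A biological difference between the knockdowns remains open as a hypothesis, as do a difference between single cultures and an indirect effect of other transcripts lowered by the siRNAs, which 1 library per group cannot separate.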

How the results depend on the processing

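Recovered RPM, with its other comparator, and the comparator without siIRX2 were chosen after seeing the data. No paired analysis was possible because each group had 1 library and no label linked libraries. Counts of genes at least 2-fold apart are given in the order differentiation, siIRX2, siIRX4 and siIRX5, where the reported counts were 374, 121, 67 and 111. They were 666, 334, 147 and 234 with a pseudocount of 0.1, which shrinks small values less, and 249, 65, 22 and 47 with a minimum of 5 FPKM, where 2685 genes were measured. They were 1052, 611, 305 and 421 with libraries rescaled to a common sum, which multiplied FPKM by 9.25 to 9.77, so that the pseudocount and the minimum weighed less and 12190 genes were measured. They were 864, 479, 173 and 320 at 1.5-fold, and 1782, 1072, 328 and 635 by reads, where 14291 genes were measured. Rescaling put 65.3% of the differentiation genes above the proliferating library, against 75.9%. Without a minimum every count was the same, which was fixed in advance. With a pseudocount of 1, a gene below 1 FPKM in all libraries cannot be 2-fold apart. With the median set to 0, after quantile normalization or with the other comparator, every count stayed within 1.5 times. For siIRX5 the reported 62 higher and 49 lower genes became 52 and 54 with the median set to 0, 53 and 53 after quantile normalization and 213 and 208 after rescaling.

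Against the mean of the other calcium-treated libraries, mitosis turned to 0.15 in siIRX4 and 0.076 in siIRX5, and DNA replication to 0.042 and 0.096. By reads they turned to 0.32 and 0.26 for mitosis and 0.048 and 0.22 for DNA replication in siIRX4 and siIRX5. With siIRX2 left out of that mean, all stayed below 0: mitosis was -0.038 and -0.11 by FPKM and -0.072 and -0.20 by reads, and DNA replication -0.10 and -0.07 by FPKM and -0.20 and -0.054 by reads, so the reversal needed siIRX2 in the comparator in both units. Mitosis in siIRX4 (percentiles 29.1 and 12.6 by FPKM and by reads) and DNA replication in siIRX5 (1.9 and 4.49) then no longer stood apart. Of 108 list results, the same call held for 101 with a pseudocount of 0.1, 100 without a minimum and 93 after rescaling. It held for 108 with the median set to 0 and 106 after quantile normalization. The rest under these settings newly stood apart (7, 8, 15, 0 and 2). That all 108 held with the median set to 0 was fixed in advance, since this shifts a list and its random lists alike. Direction was compared only for lists that stood apart in the reported setting. Lists that newly stood apart could thus change sides, as homologous recombination in siIRX2 did by reads (percentile 0.16, against 83 by FPKM). By reads 90 held, 16 newly stood apart, and WNT in siIRX5 and histones on differentiation no longer did. With the other comparator 93 held, 10 newly stood apart, WNT in siIRX5 no longer did and the 4 above reversed. With a minimum of 5 FPKM 71 of 80 held and 9 no longer stood apart: mitosis on differentiation and in siIRX4 and siIRX5, DNA replication on differentiation and in siIRX2 and siIRX5, transcription factors and wound genes on differentiation, and hypoxia in siIRX2. The smallest ratios that depth can show differ by gene: FGF18, at 9 reads in the control and 0 in siIRX2, had an upper bound of 0.549.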

Other observations

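Tests chosen only after the result was seen in this part are those of base composition and of words in the mitosis members; the genes of the opening paragraphs were ranked by reads, also after their values were seen.

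Ranked by reads, calcium differentiation brought out GABRP, a GABA receptor subunit, at 78.3 (48.7 to 135) times the proliferating library, the mucosal keratin KRT4 at 64.0 (43.2 to 99.2), the phospholipase PLA2G2F at 51.6 (38.3 to 71.2), the proton pump ATP12A at 27.8 (26.1 to 29.7) and the protease inhibitor SPINK5 at 21.3 (19.3 to 23.6). Matrix genes lay at the other end, with periostin (POSTN) at 2 reads against 231 and LOXL2 0.125 (0.107 to 0.145) and TNC 0.175 (0.166 to 0.185). In the siIRX2 library the chemokine CXCL14 had 248 reads against 7 in the control, a ratio of 38.4 (18.4 to 96.5), and STMN3 was at 8.05 (6.14 to 10.7); the cholesterol ester hydrolase NCEH1 was at 0.109 (0.0921 to 0.129), the integrin subunit ITGB8 at 0.238 (0.223 to 0.253) and the replication factor MCM10 at 0.185 (0.133 to 0.252). BTG3 and MFAP2 were lower in siIRX4, at 0.398 (0.357 to 0.444) and 0.465 (0.417 to 0.518).

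In the siIRX5 library desmoglein 1 (DSG1), an adhesion protein of suprabasal keratinocytes, had 1718 reads against 267, a ratio of 6.92 (6.08 to 7.90), and EEF1A2 5.75 (4.36 to 7.68), CALB2 5.60 (4.34 to 7.31) and COL5A3 4.11 (3.42 to 4.96) were higher too, while TCHHL1 0.195 (0.156 to 0.242), THY1 0.283 (0.209 to 0.377) and APCDD1 0.292 (0.234 to 0.363) were lower. By reads, CALB1, IL33 and CCNA1 were at least 2-fold above the shared control in each knockdown, where a single low control value is enough to give this. In the proliferating, control, siIRX2, siIRX4 and siIRX5 libraries CALB1 was at 8.92, 17.0, 72.0, 36.5 and 54.7 RPM, IL33 at 10.7, 3.48, 13.7, 10.6 and 11.03 and CCNA1 at 9.15, 4.25, 19.7, 10.1 and 15.2, so that IL33 and CCNA1 were lowest in the control. Within the cornified envelope the families differed: LCE genes (14) had a median ratio of 0.720, 1.97 and 0.295 in siIRX2, siIRX4 and siIRX5, SPRR genes (10) 0.563, 1.09 and 0.854, and the other 20 genes 0.734, 1.10 and 0.695.

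The cell cycle lists of siIRX2 were weighed against an unusual control library and against seed matches in the list members themselves. Set directly against siIRX4 and siIRX5, which leaves out the control, the mitosis list of siIRX2 had medians of -1.25 and -1.19 by reads, which argues against the control as the source. Of 30 mitosis genes, 0 carried either of the lowest words of siIRX2 in their 3' untranslated region, against 5 of 30 DNA replication genes, so direct matches by these words do not account for the mitosis list. Lower proliferation through less IRX2 stays open as a hypothesis, as do an indirect effect of other lowered transcripts and a difference between single cultures.

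The 3' untranslated region words whose carriers lay lowest as a group were ACAAGTA (z = -17.6, 1100 genes) and CAAGTAA (z = -16.7) in siIRX2 and GCAAAGA (z = -12.8) and TGCAAAG (z = -11.1) in siIRX5, while the lowest z was -6.90 in siIRX4, -5.69 in the control and -4.51 after permuting genes. Base composition of 3' UTRs was weighed by words of the same bases in another order, whose lowest z was -4.6 in siIRX2 and -3.48 in siIRX5, which argues against it. Since GC content had been adjusted for before the scan, this concerns base composition beyond GC content. Seed matches of the siRNAs, the hypothesis that the siRNAs also lowered transcripts with short matches, cannot be told apart from other sources: 4 of the 10 lowest words of siIRX2 occur in the IRX2 mRNA, between the 5 set in advance for it and the 2 set against it, where 16.6% of all words do. In siIRX5 4 of 10 words occur in the IRX5 mRNA, where 13% do. The 8-base word made of both lowest words of the library is in 4 of 4 IRX5 transcripts and in 0 of 2 IRX2 transcripts. The lowest siIRX2 word, ACAAGTA, does occur in the IRX2 coding sequence, followed by T, so the missing 8-base word does not decide the question. The siRNA sequences were not used here. In siIRX2, 179 of 440 genes at least 2-fold lower carried either word (40.7%), against 8 of 92 at least 2-fold higher (8.70%) and 16.1% of all 10941 genes, and NCEH1, SLC44A2, ITGB8, RRM2, CDT1 and BRCA2 were among the carriers. Both words were picked as the lowest of this same library, so an excess of carriers among its lower genes follows from that choice. These shares describe the size of the pattern and are no further evidence for it.

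Other explanations were examined before these and are given as values. Among lists matched on length and GC content, ribosomal protein genes lay at percentile 100 in siIRX2 and siIRX5, as among lists matched on expression alone, and in siIRX4 at 99.57, against 94.5 by reads without this matching. They were higher in siIRX2 than in siIRX4 by a median log2 ratio of 0.25. For a general delay of differentiation in siIRX5, differentiation genes were chosen without siIRX5 and the control. The 244 higher on differentiation had a median log2 ratio of -0.016 by FPKM, at percentile 0 of their random lists, with 117 higher and 125 lower. Of those random lists, 95% had medians from 0.026 to 0.086. The 84 genes lower on differentiation had a median of -0.072, also at percentile 0. The cornified envelope had a median of -0.50 by FPKM.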
